A study of Oncorhynchus mykiss with 12 samples.

How the data were processed

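Total RNA of flash-frozen rainbow trout liver was extracted with Trizol, per the labels, and made into RNA-seq and small RNA libraries, 3 control and 3 hypoxia of each kind. Group and replicate number were taken from the labels. The deposited RNA-seq table holds, per the file headers, raw counts per gene and FPKM values (counts scaled for gene length and library size) for each library. The deposited small RNA table holds raw counts and TPM values per miRNA, per the file headers, where TPM is here a count scaled to the small RNA total of the library, with no length term, listed at 0.01 for a count of 0. Both tables also hold the authors' comparison, with a log2 fold change, a p-value and an adjusted p-value. Bowtie2 2.2.8 and TopHat2 2.1.1 are named in the submitters' processing notes with no role. The quantifier, the annotation, the genome build and the authors' test are not given in the sources used here.

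The RNA-seq table had 42128 rows, 41896 with an NCBI gene number and 232 assembled loci without one. All 41896 numbers matched the reference gene table of assembly USDA_OmykA_1.1, which was used for symbols, descriptions and gene type only. No coordinates are given, since the build of the files is not given. Of the matched genes 41895 were protein coding and 0 were long noncoding RNAs, so the planned count of changed long noncoding RNAs was not made and these were not analysed here. No row carried LOC110520201 (0 rows). Gene symbols follow the files, and some differ from the description in the same row (IGFBP5 for insulin-like growth factor binding protein 1, PCK2 for phosphoenolpyruvate carboxykinase). Trout carry many near-identical gene copies, so values of single copies are uncertain where reads were split between them, above all for hemoglobins, apolipoproteins and cyp3a27. The small RNA table had 1413 rows, 540 known and 873 predicted, of which 446 shared their sequence with another row.

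The tests written before the data were examined assumed that only FPKM and TPM values would be held, and were limma on log2(FPKM + 0.5) and log2(TPM + 1). Since the tables hold counts, the main test became edgeR's quasi-likelihood test on the counts as deposited, and the limma fits are alternatives. Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Library sizes were scaled by TMM, the model held the group only, tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05 and no fold minimum. Genes with a mean FPKM of at least 0.5 (19365 genes) and miRNA rows with a mean TPM of at least 1 (510 rows, 427 distinct sequences) were tested. Each printed fold change comes from edgeR, and levels come from the deposited FPKM or TPM. The SE beside the fold change of a single gene or miRNA was derived from edgeR's F statistic. It is the absolute unshrunken log2 fold change divided by the square root of F. For sod1 and miR-2188-y an exact two-sided permutation test of the log2 values was added, for which 0.1 is the smallest possible p. Replicates of a group differed by more than counting noise in every pair (chi-square per degree of freedom of 10.5 to 24.9 in RNA-seq and 108 to 762 in small RNA). This shows that no library repeats the counts of another, and leaves open whether replicates were separate fish or repeat preparations. Each library was treated as 1 sample.

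Gene lists (26) and miRNA lists (9) of pathways and of cell types other than hepatocytes were fixed before the data were examined, with matching by symbol or by the start of the description. A description can match by its first words alone, so members that do not do what a list's name says are named in the results. Each gene list was tested with camera at a preset correlation of 0.01, with adjustment over the 26 lists. An estimated correlation and fry were the alternatives. The named genes follow a rule set before the data were examined: sod1, LOC110520201 and miR-2188-y, any miR-210, the 10 largest rises and 10 largest falls with a product name, a mean FPKM of at least 1 and groups that do not overlap, up to 4 members of each list with the smallest adjusted p, or the 2 members of highest level where none passed. For miRNAs the rule took the 5 largest changes each way past the threshold with a mean TPM of at least 10 and groups that do not overlap, the 5 of highest level and the highest of each list.

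On counts simulated from the means and spread of these libraries, edgeR called 4.48% of RNA-seq genes changed 1.5-fold, 55.2% of those changed 2-fold and 92.4% of those changed 4-fold among 19365 genes, with 6 false calls. In the small RNA comparison, 510 rows, it called 0 of 20 rows changed 1.5-fold, 1 of 20 changed 2-fold and 8 of 20 changed 4-fold, with 0 false calls, so miRNA changes up to 4-fold were mostly not detectable at this depth and spread. DESeq2 called 1, 2 and 10 of the same 20 rows, with 2 false calls. A gene list raised by 0.5 on the log2 scale in simulation was found by camera and by the estimated correlation (adjusted p = 1.04e-34 and 0.00289), with 0 other lists called. Genes were drawn independently in that simulation. In the real libraries the estimated correlation of list members ran from -0.0019 (interferon and antigen presentation) to 0.487 (ribosomal proteins). The simulation therefore cannot show how often camera at its preset correlation calls lists wrongly where members move together.

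Alternatives fixed beforehand were other pseudocounts, filters, scalings (median-of-ratios, run on the counts, and quantile normalization), limma without a trend or with array quality weights, a fold minimum, a replicate block and leaving out each library in turn. Alternatives chosen after seeing the data were the limma fits as first written, DESeq2, library totals without TMM, 1 row per distinct small RNA sequence, known miRNAs alone, and the small RNA fit without both libraries numbered 3.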

Results

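Liver RNA of rainbow trout (Oncorhynchus mykiss) was profiled in a control group and in a group kept under moderate hypoxia for 1 month, at 4.5 ± 0.1 mg/L dissolved oxygen per the labels. Each group had 3 RNA-seq libraries and 3 small RNA libraries, 12 libraries in all. The RNA-seq counts summed to 19060468 to 23152833 per library and the miRNA counts to 8822671 to 13614506. A group of the same study at 12 h of hypoxia was not analysed here. The labels do not say whether replicates were separate fish, so p-values measure only the spread between these samples, which may be technical. Levels below are means ± SD of 3 libraries per group, in the authors' FPKM for genes and TPM for miRNAs, and fold changes are log2 of hypoxia over control from edgeR.

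The first comparison asked which liver transcripts differ after 1 month of low oxygen. Higher in hypoxia were 24 of 56 cell cycle genes (0 lower), 9 of 46 genes of cholesterol synthesis (1 lower) and 17 of 89 genes of heat shock and endoplasmic reticulum stress (4 lower), and among single genes PHGDH and PSPH of serine synthesis, erythropoietin and insulin-like growth factor binding protein 1. Lower were 19 of 23 hemoglobin loci, 7 of 54 genes of fatty acid oxidation (1 higher), 10 of 106 genes of bile acid and xenobiotic metabolism (5 higher) and 13 of 84 stellate cell and matrix genes (0 higher), and among single genes apolipoproteins A-I and A-IV and glucose-6-phosphatase. No list had an adjusted p under 0.05 with an estimated correlation (0 of 26 lists, against 13 by camera at its preset correlation and 4 by fry). Splits of the 6 libraries that mix the 2 groups also gave 5 to 10 lists by camera at its preset correlation. Of 19365 genes tested, 1398 passed an adjusted p of 0.05 in edgeR, 741 higher and 657 lower in hypoxia, and 476 of them changed at least 2-fold (320 higher, 156 lower). The authors' deposited table has 1400 genes past the same threshold (714 higher, 686 lower), of which 1178 were also called here, all 1178 in the same direction. On the first principal component, with 44.1% of the variance, control replicate 1 lay at -9.57, between the other controls (-41.8 and -38.7) and the hypoxia libraries (24.9 to 33.2). Leaving out 1 library gave 2186 genes without control replicate 1, 473 without control replicate 2, 496 without control replicate 3, 361 without hypoxia replicate 1, 472 without hypoxia replicate 2 and 432 without hypoxia replicate 3. Of the 98 named genes other than sod1, 37 kept direction and side of the threshold in all 6 of these fits. A fit with 1 library fewer has less power, so a lost call does not by itself show dependence on that library. Genes at an unadjusted edgeR p under 0.05 numbered 4581 with all libraries and 3484 to 5143 with 1 left out.

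Among the 10 largest rises, 6 were genes of DNA replication or cell division. The transcript of cdca7a (NCBI gene 110520115), a cell division cycle associated gene, rose by 3.15 (SE 0.49) on the log2 scale, from 0.209 ± 0.199 to 1.84 ± 0.348 FPKM, with an edgeR adjusted p of 0.00837. Subunits of the MCM helicase, which unwinds DNA for replication, rose together: mcm2 by 2.97 and 2.72 at its 2 loci, mcm3 by 2.58 and mcm5 by 2.56. Gins4, a partner of that helicase, rose by 2.39 (SE 0.31). Both PHGDH and PSPH, the first and last enzymes of serine synthesis from 3-phosphoglycerate, were in this group. PHGDH (110520091) rose by 2.59 (SE 0.26), from 2.92 ± 1.35 to 17.6 ± 1.70 FPKM (edgeR adjusted p = 0.00247), and PSPH rose by 2.43 (SE 0.47). The stress gene ddit4 (110531799), an inhibitor of mTORC1, rose by 2.65 (SE 0.63) from 1.61 ± 1.14 to 10.1 ± 9.20 FPKM (edgeR adjusted p = 0.0318), with 3.46, 6.27 and 20.6 FPKM in the hypoxia libraries. Its adjusted p was 0.117 at a log2 fold change of 1.63 without hypoxia replicate 3, 0.083 without control replicate 2, 0.0901 without control replicate 3 and 0.0566 without hypoxia replicate 2. The nuclear import factor NUTF2 completed the group at 2.39 (SE 0.65, edgeR adjusted p = 0.047). It lost its call in 5 of the 6 fits without 1 library, with adjusted p of 0.0737 and 0.0745 without control replicates 2 and 3, and 0.135, 0.0758 and 0.15 without hypoxia replicates 1, 2 and 3. PSPH lost its call in 2 of them.

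Apolipoprotein transcripts were among the 10 largest falls, beside transcripts of other kinds. Transcripts of apolipoprotein A-IV, a component of lipoprotein particles, fell by 4.30 (SE 0.88) at LOC110523359, by 3.05 (SE 0.50) at LOC110537912 and by 2.52 (SE 0.45) at LOC110510198, and LOC110537912 went from 281 ± 223 to 34.8 ± 2.98 FPKM. Control replicate 1 had 86.5 FPKM at this locus, against 525 and 233 FPKM in the other controls. At LOC110523359 it had 1.575 FPKM, against 42.4 and 17.0 FPKM in the other controls. That is near the hypoxia libraries, at 1.278, 0.896 and 1.026 FPKM. The apolipoprotein A-I transcript apoa-i-2 (100135865) fell by 2.22 (SE 0.16), from 914 ± 159 to 199.9 ± 9.70 FPKM, with the smallest adjusted p of all genes (edgeR, 0.000368). The transcript mid1ip1a (110508116), described as thyroid hormone responsive and of a family tied to fat synthesis, fell by 2.36 (SE 0.25), from 1456.5 ± 489.5 to 288 ± 60.2 FPKM (edgeR adjusted p = 0.00323). Hemoglobin alpha (hba, 110486351) fell by 2.66 and hemoglobin beta (hbb1, 110486350) by 2.36. The other large falls were gatm, an enzyme of creatine synthesis (fell by 2.42, SE 0.28), a type-4 ice-structuring protein at LOC110487688 (fell by 2.35, SE 0.43) and the basement membrane chain LAMB3 (fell by 2.27, SE 0.44). LOC110523359 lost its call without any 1 of the hypoxia libraries, with edgeR adjusted p of 0.08, 0.0719 and 0.0835 without replicates 1, 2 and 3. Of the 6 fits without 1 library, 3 ended the call of LOC110510198, 2 that of LAMB3 and 1 each those of LOC110537912 and LOC110487688.

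**Figure D1:**
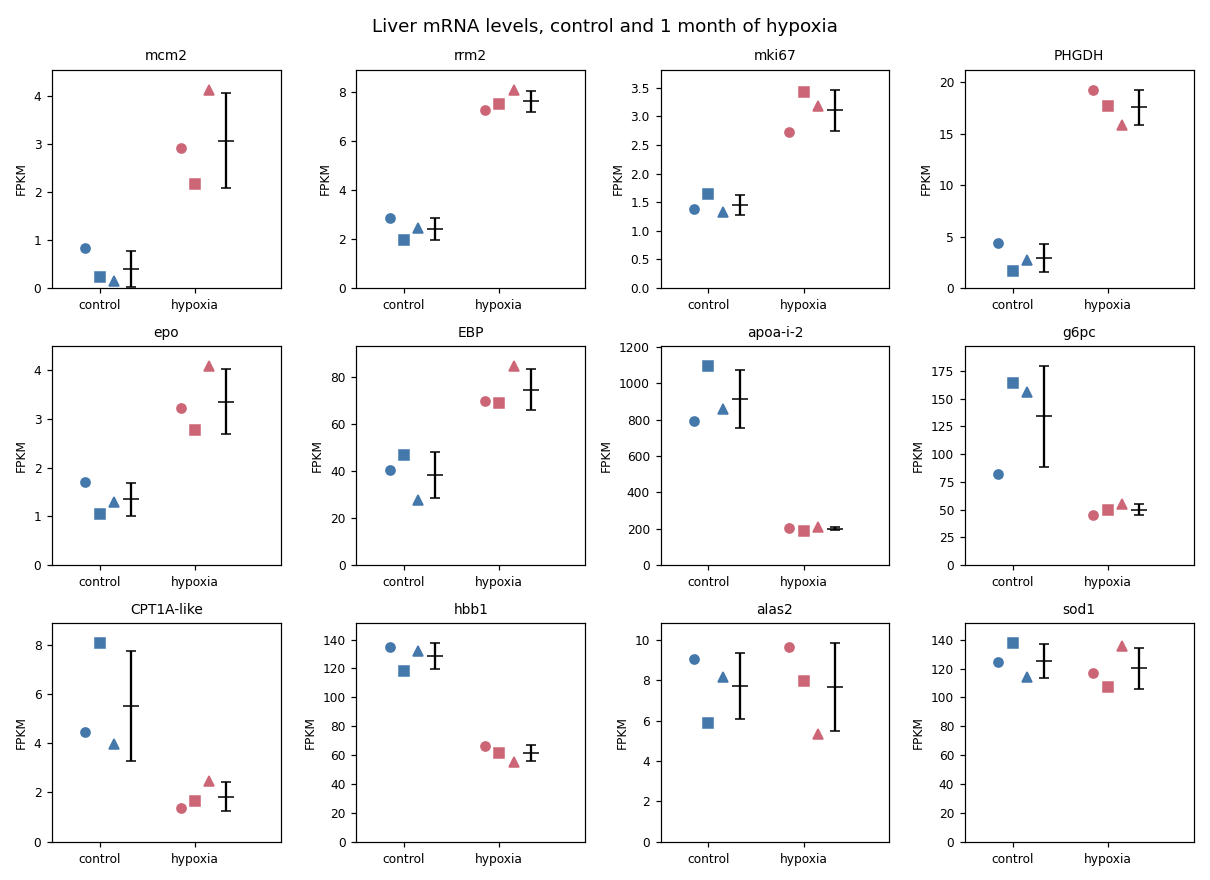
Levels of 12 genes in FPKM (vertical axes, linear and starting at 0) in each RNA-seq library of the control (blue) and hypoxia (red) groups. Circles, squares and triangles are replicates 1, 2 and 3, and the black bars give the mean and SD. PHGDH went from 2.92 to 17.6 FPKM and apoa-i-2 from 914 to 199.9 FPKM with no overlap of the groups, while the values of sod1 and alas2 overlapped.

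The list for the hypoxia-inducible factor (HIF) pathway covers the transcriptional response to low oxygen. Of its 50 tested members 6 rose and 1 fell, and 9 rose and 2 fell when adjusted over the list alone. The hormone of red cell formation, epo (110531655), rose by 1.31 (SE 0.20), from 1.35 ± 0.335 to 3.36 ± 0.664 FPKM (edgeR adjusted p = 0.00839). Insulin-like growth factor binding protein 1 rose by 1.75 (SE 0.40) at the locus with the file symbol IGFBP5 and by 1.52 (SE 0.36) at igfbp1a. Without hypoxia replicate 3, which had 38.3 FPKM of igfbp1a against 11.8 and 14.8 FPKM in the other hypoxia libraries, igfbp1a was at 0.844 (edgeR adjusted p = 0.0524), and its adjusted p was 0.0918 and 0.0794 without control replicates 2 and 3. The IGFBP5 locus lost its call without control replicate 3 (0.0863) and without hypoxia replicates 1, 2 and 3 (0.0637, 0.0668 and 0.0988), and Bnip3 in 2 of the 6 fits. Bnip3, a mitophagy receptor, fell by 1.07 (SE 0.20), from 66.3 ± 16.4 to 32.2 ± 3.19 FPKM. The median of the list was 0.11 and the list test gave a camera adjusted p of 0.110, or 0.674 with an estimated correlation. The camera adjusted p was 0.0352 without control replicate 1 and 0.0251 without hypoxia replicate 1. The HIF list had 10, 2 and 2 higher and 1, 1 and 2 lower in edgeR without control replicates 1, 2 and 3, and 5, 3 and 1 higher and 0, 1 and 0 lower without hypoxia replicates 1, 2 and 3.

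Genes of glucose metabolism went both ways. Glycolysis members went both ways, 3 higher and 4 lower of 42, and 4 and 4 when adjusted over the list alone. The most abundant copy of gapdh among the named genes (110496191) fell by 1.19 (SE 0.17), from 374 ± 60.2 to 167 ± 17.7 FPKM, and a second copy by 0.98 (SE 0.14), while pgam1b rose by 1.08 (SE 0.17) and tpi1b by 1.07 (SE 0.21). The list median was 0.06, with a camera adjusted p of 0.890. Glycolysis had 5, 2 and 2 higher and 5, 2 and 2 lower in edgeR without control replicates 1, 2 and 3, and 2, 1 and 1 higher and 2, 2 and 2 lower without hypoxia replicates 1, 2 and 3. Gluconeogenesis and glycogen genes, 41 tested, had 2 higher and 4 lower, or 2 and 10 when adjusted over the list alone. Glucose-6-phosphatase, which releases free glucose from the liver, fell by 1.44 (SE 0.24) at g6pc (100135885), from 134 ± 45.2 to 49.9 ± 4.87 FPKM, and by 1.23 (SE 0.28) at a second copy. Phosphoenolpyruvate carboxykinase fell by 0.67 (SE 0.16) and the branching enzyme gbe1b by 0.56 (SE 0.14). This list had a median of -0.19 and a camera adjusted p of 0.0475, with an adjusted p = 0.674 with an estimated correlation. Its camera adjusted p was above 0.05 without control replicate 1 (0.118), control replicate 2 (0.0708), hypoxia replicate 1 (0.166) and hypoxia replicate 2 (0.0528), with quantile normalization in limma (0.117) and with no filter (0.220, median -0.05). The gluconeogenesis list had 4, 0 and 0 higher and 8, 1 and 1 lower in edgeR without control replicates 1, 2 and 3, and 0, 0 and 0 higher and 0, 1 and 3 lower without hypoxia replicates 1, 2 and 3. PCK2 and gbe1b lost their calls in 5 of the 6 fits without 1 library, the second glucose-6-phosphatase copy in 4, tpi1b in 2 and g6pc in 1.

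Mitochondrial lists had few members past the threshold. In the TCA cycle list, 1 of 68 members, ogdh (fell by 0.62, SE 0.15), was lower and none higher in edgeR, and 0 passed when adjusted over the list alone. The median of this list was -0.03, its mean 0.0021 and its camera direction down (camera adjusted p = 0.890). The TCA list had 0, 0 and 0 higher and 4, 0 and 0 lower in edgeR without control replicates 1, 2 and 3, and 0, 0 and 0 higher and 0, 0 and 0 lower without hypoxia replicates 1, 2 and 3. Subunits of the electron transport chain and ATP synthase had 3 of 148 higher and 0 lower, with 2 higher when adjusted over the list alone: COX7A2 rose by 0.87 (SE 0.13), COX6B1 by 0.58 (SE 0.12) from 174 ± 4.996 to 264 ± 14.1 FPKM, and Atp5po by 0.56 (SE 0.13). The median of the subunits was 0.14 with a camera adjusted p of 0.00772, which became an adjusted p = 0.796 with an estimated correlation and a camera adjusted p of 0.674 without control replicate 1. Electron transport and ATP synthase had 3, 1 and 2 higher and 1, 0 and 0 lower in edgeR without control replicates 1, 2 and 3, and 1, 2 and 1 higher and 0, 0 and 0 lower without hypoxia replicates 1, 2 and 3. Calls of ogdh and Atp5po were lost in 5 of the 6 fits without 1 library, and that of COX6B1 in 4.

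Most members of the lipid lists did not pass. Fatty acid oxidation members were 1 higher and 7 lower of 54, and 1 and 12 when adjusted over the list alone. A carnitine palmitoyltransferase I gene (file symbol CPT1A, 100329197), which admits fatty acids to mitochondria, fell by 1.61 (SE 0.29), from 5.49 ± 2.23 to 1.83 ± 0.578 FPKM. The receptor pparab fell by 0.68, the electron carrier etfb by 0.63 and the peroxisomal enzyme ehhadh by 0.73. The median was -0.21, the camera adjusted p 0.0013 and the adjusted p = 0.674 with an estimated correlation. Fatty acid oxidation had 2, 0 and 0 higher and 12, 2 and 1 lower in edgeR without control replicates 1, 2 and 3, and 0, 0 and 0 higher and 1, 1 and 2 lower without hypoxia replicates 1, 2 and 3. Cholesterol synthesis had 9 higher and 1 lower of 46, and 14 and 1 when adjusted over the list alone. EBP, a sterol isomerase, rose by 0.95 (SE 0.17) from 38.3 ± 9.62 to 74.6 ± 8.68 FPKM, sc5d by 0.94 (SE 0.15), Nsdhl by 1.40 (SE 0.32) and acat2 by 0.68 (SE 0.16). The 1 lower member, Lrp5 (named after its value was seen), matched by the start of its description and encodes a receptor of the LDL receptor family that is known as a Wnt coreceptor. The list median was 0.38 with a camera adjusted p of 4.84e-06, and an adjusted p = 0.674 with an estimated correlation. Without control replicate 1 it had 20 members higher, and without any 1 of the other 5 libraries 2, with 0 lower in edgeR in each of these fits. Of the 44 genes of fatty acid and triglyceride synthesis, 4 rose and 7 fell, or 7 and 12 when adjusted over the list alone. Triglyceride synthesis enzymes were among the falls, with dgat2 at -0.71 and -0.79 at 2 loci and Lpin2 at -0.80, as was ACACB at -0.75. That list had a median of -0.08 (camera adjusted p = 0.409). It had 11, 0 and 0 higher and 10, 3 and 5 lower in edgeR without control replicates 1, 2 and 3, and 0, 0 and 0 higher and 2, 2 and 7 lower without hypoxia replicates 1, 2 and 3. Single genes also lost their calls in fits without 1 library: etfb, ehhadh, Nsdhl, acat2 and ACACB in 5 of the 6, pparab in 3, and CPT1A, EBP and both dgat2 loci in 1 each.

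Bile acid and xenobiotic metabolism had 5 higher and 10 lower members of 106, and 11 and 23 when adjusted over the list alone. Cytochrome cyp2k5 (100137012) fell by 1.23 (SE 0.13), from 291 ± 18.6 to 127 ± 11.6 FPKM (edgeR adjusted p = 0.0033). CYP7A1, the rate-limiting enzyme of bile acid synthesis, fell by 1.04 (SE 0.20), and cyp3a27 fell by 0.81 and 0.76 at 2 loci that are near-copies and may share reads. The median was -0.19, with a camera adjusted p of 0.0147 and an adjusted p = 0.220 with an estimated correlation. Bile acid and xenobiotic genes had 11, 0 and 1 higher and 19, 4 and 2 lower in edgeR without control replicates 1, 2 and 3, and 1, 1 and 2 higher and 2, 1 and 1 lower without hypoxia replicates 1, 2 and 3. Amino acid catabolism had 3 higher and 5 lower of 59, and 4 and 7 when adjusted over the list alone, with a median of -0.08 (camera adjusted p = 0.647). Amino acid catabolism had 4, 3 and 2 higher and 9, 3 and 1 lower in edgeR without control replicates 1, 2 and 3, and 1, 2 and 1 higher and 1, 0 and 1 lower without hypoxia replicates 1, 2 and 3. In it the glycine cleavage enzyme GLDC fell by 0.82 (SE 0.14), while FAH rose by 0.70, sdsl by 0.96 and a CBS copy of low level by 1.92, from 0.334 ± 0.202 to 1.26 ± 0.284 FPKM. Both cyp3a27 loci lost their calls in 5 of the 6 fits without 1 library, CYP7A1 and sdsl in 3, FAH in 2, and GLDC and CBS in 1.

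The cell cycle list had the largest median change of the 26 fixed lists, in either direction. Of 56 members 24 rose and none fell in edgeR, and 34 rose when adjusted over the list alone, with a median of 0.82. The nucleotide enzymes rrm2 and tyms rose by 1.64 (SE 0.16) and 1.43 (SE 0.18), and the proliferation marker mki67 by 1.08 (SE 0.16), from 1.45 ± 0.169 to 3.11 ± 0.358 FPKM. The camera adjusted p was 2.65e-20, with an adjusted p = 0.220 with an estimated correlation. Without control replicate 1, 20 members were higher and 1 lower. Those higher numbered 14 without control replicate 2, 13 without control replicate 3, 20 without hypoxia replicate 1, 13 without hypoxia replicate 2 and 9 without hypoxia replicate 3. The leukocyte list had a median of 0.04 and the red blood cell list one of -0.65 in the same libraries. Ribosomal proteins had 3 higher and 0 lower of 198, with 1 higher when adjusted over the list alone. These were rps13, which rose by 0.53 (SE 0.13), rpl7l1, an assembly factor related to L7, which rose by 0.93 (SE 0.15), and RPS19BP1, described as a regulator of SIRT1, which rose by 1.27 (SE 0.28). The median of 0.15 had a camera adjusted p of 0.0011, an adjusted p = 0.796 with an estimated correlation, and a camera adjusted p of 0.518 without control replicate 1. The ribosomal list had 3, 1 and 2 higher and 1, 0 and 0 lower in edgeR without control replicates 1, 2 and 3, and 1, 2 and 1 higher and 0, 0 and 0 lower without hypoxia replicates 1, 2 and 3. Among the 3 ribosomal list genes, rps13 and RPS19BP1 lost their calls in 5 of the 6 fits without 1 library.

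Heat shock and endoplasmic reticulum (ER) stress genes rose in 17 and fell in 4 of 89 cases, and in 22 and 4 when adjusted over the list alone. The mitochondrial chaperone HSPA9 rose by 1.27 (SE 0.16), the collagen chaperone hsp47 by 1.26 (SE 0.19) and the ER chaperone calreticulin by 1.39 (SE 0.21) and 0.84 (SE 0.13) at 2 loci. The 4 falls, named after their values were seen, were the stress regulators xbp1 (-0.83), DDIT3 (-0.67) and Atf6b (-0.86) and the cochaperone dnajb1b (-0.91). The median of 0.19 had a camera adjusted p of 0.00126, with an adjusted p = 0.315 with an estimated correlation. The heat shock list had 16, 6 and 7 higher and 5, 1 and 0 lower in edgeR without control replicates 1, 2 and 3, and 6, 7 and 8 higher and 0, 0 and 1 lower without hypoxia replicates 1, 2 and 3. Antioxidant defence had 8 higher and 9 lower of 99, and 12 and 12 when adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.473). The antioxidant list had 12, 3 and 0 higher and 12, 0 and 2 lower in edgeR without control replicates 1, 2 and 3, and 0, 0 and 5 higher and 2, 0 and 0 lower without hypoxia replicates 1, 2 and 3. The mitochondrial peroxidase PRDX3 rose by 0.73 and 0.69 at 2 loci and a glutathione S-transferase (file symbol GSTA2) by 0.73, while the ferritin middle subunit, an iron store, fell by 0.90 (SE 0.18) from 170.2 ± 39.6 to 94.4 ± 8.75 FPKM. The ferritin call was lost in 5 of the 6 fits without 1 library, those of PRDX3 in 3 and 4, and that of GSTA2 in 3.

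In the immune and apoptosis lists some members rose and some fell. Over all genes 1398 of 19365 passed in edgeR. Complement and acute phase genes, 108 tested, had 6 higher and 3 lower, or 8 and 6 when adjusted over the list alone. Among them a complement C1q-like protein 3 (LOC100136613) rose by 1.42 (SE 0.21), from 1490.5 ± 432 to 4000.3 ± 694 FPKM, Fgg, a fibrinogen chain, rose by 0.93 and C1qbp, a mitochondrial protein that binds C1q, rose by 0.68, while the chemotactic factor lect2 fell by 1.40 (SE 0.34) from 1488.8 ± 926 to 564 ± 156 FPKM. Without control replicate 1, which had 2537.8 FPKM, lect2 was at -0.826 (edgeR adjusted p = 0.0331), and its call was lost in 4 of the other 5 fits without 1 library. Their median was -0.03 (camera adjusted p = 0.957). The complement list had 7, 2 and 2 higher and 11, 0 and 1 lower in edgeR without control replicates 1, 2 and 3, and 1, 3 and 1 higher and 0, 1 and 2 lower without hypoxia replicates 1, 2 and 3. Interferon and antigen presentation genes had 4 higher and 4 lower of 106, or 5 and 4 when adjusted over the list alone, with a median of 0.05 (camera adjusted p = 0.647). Interferon and antigen presentation had 5, 0 and 0 higher and 5, 1 and 1 lower in edgeR without control replicates 1, 2 and 3, and 0, 2 and 0 higher and 1, 1 and 2 lower without hypoxia replicates 1, 2 and 3. With all libraries those called included IFRD1 (fell by 0.98), trim25 (fell by 0.64) and a class I histocompatibility gene (rose by 1.00). IFRD1 is known as a transcriptional coregulator. The apoptosis list had 1 higher and 2 lower of 62, and 1 and 2 when adjusted over the list alone: cdkn1ba, a cell cycle inhibitor, rose by 0.83, and badb fell by 1.01 beside Bnip3. Its median was -0.02, its mean 0.02 and its camera direction down (camera adjusted p = 0.957). The apoptosis list had 2, 0 and 1 higher and 3, 1 and 1 lower in edgeR without control replicates 1, 2 and 3, and 0, 1 and 0 higher and 0, 1 and 0 lower without hypoxia replicates 1, 2 and 3. Estrogen response and egg protein genes had 0 higher and 2 lower of 13, and 0 and 2 when adjusted over the list alone. These were a vitelline envelope protein (file symbol ZP4, fell by 1.02, SE 0.16) and estrogen receptor erb2 (fell by 0.48, SE 0.12), in a list with a median of -0.05 (camera adjusted p = 0.185, or 0.0268 without control replicate 1). The estrogen list had 1, 0 and 0 higher and 5, 1 and 1 lower in edgeR without control replicates 1, 2 and 3, and 0, 0 and 0 higher and 1, 1 and 1 lower without hypoxia replicates 1, 2 and 3. Fits without 1 library ended the calls of trim25, badb, cdkn1ba and erb2 in 5 of 6 cases, those of IFRD1 and the class I gene in 4, those of Fgg and C1qbp in 3 and that of Bnip3 in 2.

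Markers of cell types other than hepatocytes were tested in the same way. In the red blood cell list 20 of 43 members fell and 0 rose, with 23 falls when adjusted over the list alone. Of the 20 falls 19 were hemoglobin loci, and the 20 members other than hemoglobins had a mean change of -0.0269 (SE 0.0989), with 1 lower, NT5C3A (named after its value was seen). Hemoglobin beta hbb1 (100301726) fell by 1.09 (SE 0.13), from 128 ± 9.09 to 61.2 ± 5.53 FPKM, and hemoglobin alpha hba (110486354) by 1.29 (SE 0.17). The hemoglobin loci are near-identical copies that may share reads, and the summed counts of 23 loci fell by 0.95 (SE 0.20) on the log2 scale. The median of the list was -0.65, with a camera adjusted p of 1.41e-12 and an adjusted p = 0.315 with an estimated correlation. Its falls numbered 21, 18 and 11 without control replicates 1, 2 and 3, and 12, 12 and 11 without hypoxia replicates 1, 2 and 3. Stellate cell and matrix genes fell in 13 and rose in 0 of 84 cases, with 26 falls when adjusted over the list alone. SPARC fell by 0.62 (SE 0.12), COL6A2 by 0.76 (SE 0.16), COL13A1 by 0.64 (SE 0.14) and the matrix protease MMP2 by 0.76 (SE 0.17). The median of -0.33 had a camera adjusted p of 9.1e-07, with an adjusted p = 0.315 with an estimated correlation. Of these 84 genes edgeR called 11 lower without control replicate 1, 1 without control replicate 2 and 6 without control replicate 3. Without hypoxia replicates 1, 2 and 3 it called 0, 0 and 6 lower. The list test still passed without hypoxia replicate 1 or 2 (camera adjusted p = 1.97e-05 and 1.04e-06). Endothelial genes had 1 fall in 27, CDH5 (fell by 0.53, SE 0.14), 0 when adjusted over the list alone, a median of -0.21, a camera adjusted p of 0.00541 and an adjusted p = 0.315 with an estimated correlation. Endothelial genes had 0, 0 and 0 higher and 1, 0 and 0 lower in edgeR without control replicates 1, 2 and 3, and 0, 0 and 0 higher and 0, 0 and 0 lower without hypoxia replicates 1, 2 and 3. COL13A1, MMP2 and CDH5 lost their calls in 5 of the 6 fits without 1 library, SPARC in 4 and COL6A2 in 3.

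Leukocyte genes had 0 higher and 2 lower of 55, and 0 and 2 when adjusted over the list alone, with a median of 0.04 (camera adjusted p = 0.957). The leukocyte list had 0, 0 and 0 higher and 2, 1 and 1 lower in edgeR without control replicates 1, 2 and 3, and 0, 0 and 0 higher and 1, 1 and 2 lower without hypoxia replicates 1, 2 and 3. The 2 lower with all libraries were the macrophage receptor Marco, which fell by 1.35 (SE 0.19), and igsf9b, a neural adhesion gene matched by its description, which fell by 1.04. Bile duct markers had 1 fall in 29, also when adjusted over the list alone, at the claudin with the file symbol CLDN3 (fell by 2.02, SE 0.49), with a median of -0.19 (camera adjusted p = 0.110). Without control replicate 1, at 1.82 FPKM against 0.477 and 0.635 FPKM in the other controls, CLDN3 was at -1.28 (edgeR adjusted p = 0.0617). Its adjusted p was 0.0511 without control replicate 3 and 0.101, 0.085 and 0.125 without hypoxia replicates 1, 2 and 3. The bile duct camera adjusted p was 0.011 without control replicate 2, 0.028 without control replicate 3 and 0.0424 with no filter. The bile duct list had 2, 0 and 0 higher and 0, 1 and 0 lower in edgeR without control replicates 1, 2 and 3, and 0, 0 and 0 higher and 0, 0 and 0 lower without hypoxia replicates 1, 2 and 3. Exocrine pancreas genes had 1 fall in 21, also when adjusted over the list alone, at trypsinogen trp3 (fell by 1.35, SE 0.25), and a median of -0.22. The camera adjusted p of 0.0348 became an adjusted p = 0.793 with an estimated correlation, and a camera adjusted p of 0.170 without control replicate 2, 0.0507 without control replicate 3, 0.964 without hypoxia replicate 1, 0.0539 with quantile normalization in limma and 0.0783 at a mean FPKM of at least 2. Exocrine pancreas had 0, 0 and 0 higher and 1, 1 and 1 lower in edgeR without control replicates 1, 2 and 3, and 0, 0 and 0 higher and 0, 0 and 1 lower without hypoxia replicates 1, 2 and 3. Calls of igsf9b were lost in 4 and of trp3 in 2 of the 6 fits without 1 library. Skeletal muscle had no call in edgeR or when adjusted over the list alone among 7 genes, with ATP2A1 at -0.21 (edgeR adjusted p = 0.447) and myl1 at -0.50 (edgeR adjusted p = 0.729), and here the median was 0.07, the mean -0.11 and the camera direction down (camera adjusted p = 0.957).

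Secreted hepatocyte products had 5 higher and 10 lower of 61, and 5 and 14 when adjusted over the list alone. Apolipoproteins A-I and A-IV made up most of the named falls, with LOC110537898 (fell by 2.02, SE 0.30) and LOC110510190 (fell by 2.21, SE 0.38) beside those given above, while apoe, named after its value was seen, rose by 1.20. The list had a median of -0.07 and a mean of -0.36, with a camera adjusted p of 0.0301 and an adjusted p = 0.796 with an estimated correlation. Its camera adjusted p was 0.166 without control replicate 3, 0.084 without hypoxia replicate 1 and 0.193 without hypoxia replicate 3. Of 11 alternatives that keep every library and the preset correlation, 6 also ended this call: the limma fit as first written and without a trend (0.106 in both), pseudocounts of 0.1 and 1 (0.102 and 0.115), quantile normalization (0.117) and a mean FPKM of at least 2 (0.0783). The list test kept the trend in both of the first 2, so these are 1 calculation and not 2. LOC110510190 lost its call in 2 of the 6 fits without 1 library. The hepatocyte list had 5, 3 and 3 higher and 14, 6 and 7 lower in edgeR without control replicates 1, 2 and 3, and 2, 1 and 0 higher and 3, 4 and 2 lower without hypoxia replicates 1, 2 and 3. In all, camera called 13 of the 26 lists (5 up, 8 down) at its preset correlation and 0 with correlations estimated from the data, and fry called 4. The calls of fry, which asks whether the genes of a list move on balance one way, were the cell cycle, bile acid and xenobiotic, endothelium and stellate cell lists.

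**Figure D2:**
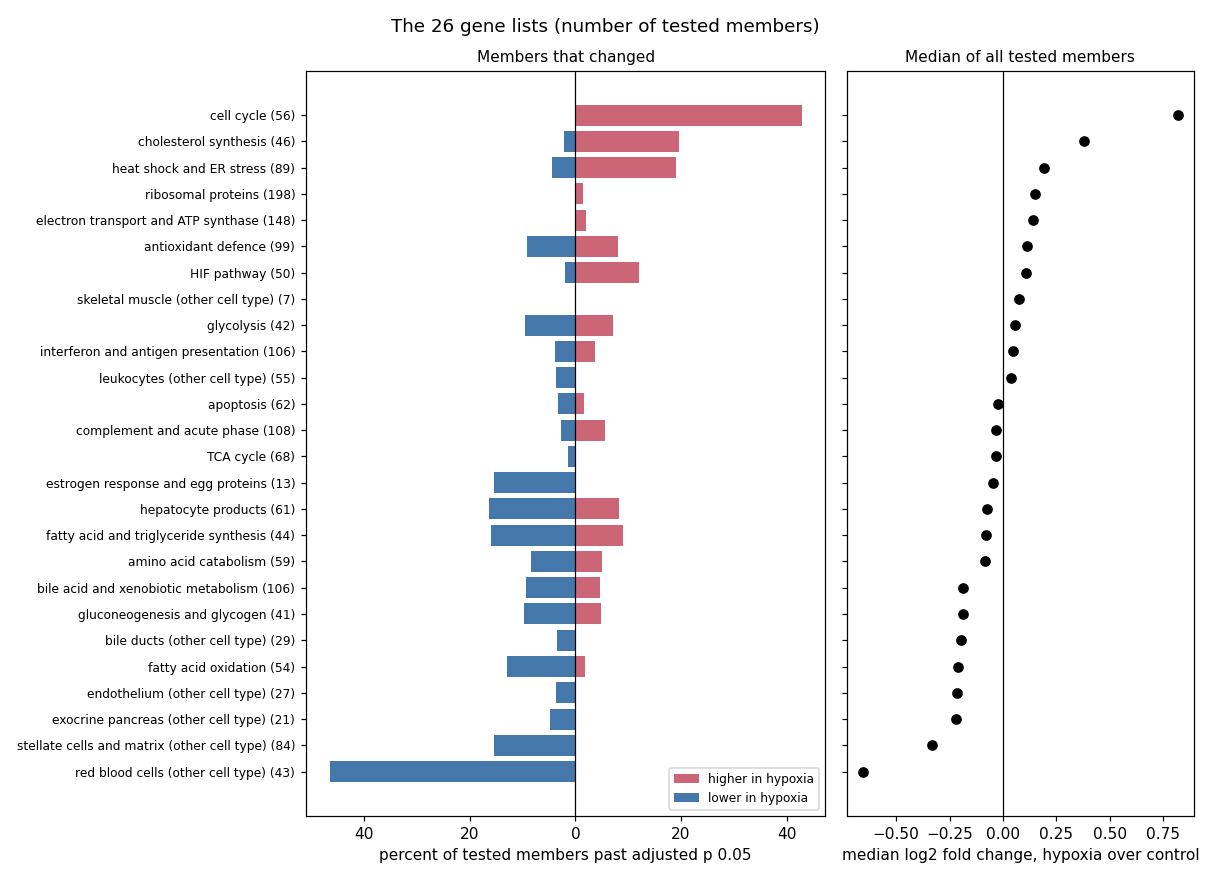
The 26 gene lists, with the number of tested members in brackets. Left, the percent of members that passed an edgeR adjusted p of 0.05, with rises to the right in red and falls to the left in blue. Right, the median log2 fold change of all tested members, from -0.65 for red blood cells to 0.82 for the cell cycle.

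The study also asked about a proposed axis of a long noncoding RNA, LOC110520201, a microRNA, miR-2188-y, and superoxide dismutase 1, sod1, an enzyme that removes superoxide. The transcript sod1 (100135992) showed no difference beyond the spread between libraries, with 125 ± 11.9 FPKM in control and 120 ± 14.4 FPKM in hypoxia. Its log2 fold change was -0.10 (SE 0.13, edgeR adjusted p = 0.697). An exact two-sided permutation test of the 6 values gave p = 0.7, where 0.1 is the smallest value 3 against 3 libraries allow. Without control replicate 2 the log2 fold change was 0.0016, with the sign turned. The mean of miR-2188-y was lower in hypoxia, at 44.0 ± 15.3 against 65.6 ± 19.6 TPM, but the groups overlapped and the log2 fold change of -0.71 (SE 0.38) did not pass (edgeR adjusted p = 0.548). Without both small RNA libraries numbered 3 it was -0.205 (edgeR adjusted p = 0.902). The exact two-sided permutation test of all 6 values gave p = 0.2. LOC110520201 was not analysed here.

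The small RNA comparison asked which miRNAs differ between the same conditions. The liver miRNA miR-122-x dominated both groups, at 511488 ± 57164 TPM in control and 455637 ± 14633 TPM in hypoxia (log2 fold change -0.27, edgeR adjusted p = 0.648). Of 510 miRNA rows tested, 286 known and 224 predicted by the authors, 1 passed in edgeR. It was miR-4454-z, which rose by 1.74 (SE 0.23), from 36.7 ± 10.2 to 127.7 ± 16.6 TPM (edgeR adjusted p = 0.0241). A further look at unadjusted p under 0.05 gave 45 rows by edgeR, and DESeq2 called 6 rows after adjustment. The authors' deposited table has 0 rows past the same threshold, with 67 rows at an unadjusted p under 0.05 and a smallest adjusted value of 0.0697. No row passed in edgeR after leaving out any 1 library (0 each time), with 58, 77 and 51 rows at an unadjusted p under 0.05 without control replicates 1, 2 and 3, and 28, 31 and 32 without hypoxia replicates 1, 2 and 3. Small RNA control replicate 3 stood apart, at 25.8 on the first principal component against -7.43 to -2.14 for the rest, with 846 rows detected against 1096 to 1163.

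The hypoxia-associated family miR-210 had log2 fold changes of 0.55 (SE 0.33) for miR-210-x, 1.27 (SE 0.26) for miR-210-y and 1.16 (SE 0.26) for miR-210-z, none past the threshold in edgeR with all libraries (adjusted p = 0.554, 0.203 and 0.214). Without both libraries numbered 3, a fit chosen after seeing the data, miR-210-y passed in edgeR at 1.23 (adjusted p = 0.0427). Over all alternatives its adjusted p ranged from 0.00109 in DESeq2 to 0.8295 without hypoxia replicate 1. DESeq2 gave adjusted p of 0.00109 for miR-210-y and 0.0178 for miR-210-z. The level of miR-210-y was 41.1 ± 10.01 TPM in control and 104 ± 24.0 TPM in hypoxia. Among the most abundant miRNAs the log2 fold changes were -0.10 for miR-22-y, 0.46 for miR-199-x (edgeR adjusted p = 0.386), 0.41 for miR-192-x and 0.07 for miR-30-x, none past the threshold.

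Of the 9 miRNA lists fixed beforehand, none had a member past the threshold over all rows in edgeR. When adjusted over the list alone, 3 of 14 hypoxia and fish stress miRNAs passed, 1 of 8 red blood cell miRNAs, 2 of 15 endothelial and stromal miRNAs and 2 of 3 let-7 rows. In the liver (19 rows), leukocyte (11), muscle (5), pancreas (5) and epithelial and bile duct (9) lists 0 passed in edgeR, with 3, 0, 1, 0 and 2 rows at an unadjusted p under 0.05, and none of the 6 rows DESeq2 called belonged to these lists. The members of highest level had log2 fold changes of 0.20 for miR-16-x in red blood cells, 0.09 for miR-181-x in leukocytes, 0.94 for miR-499-x in muscle, -0.02 for miR-375-y in pancreas, 0.50 for miR-200-y in epithelium and -0.45 for let-7-x, none past the threshold.

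**Figure D3:**
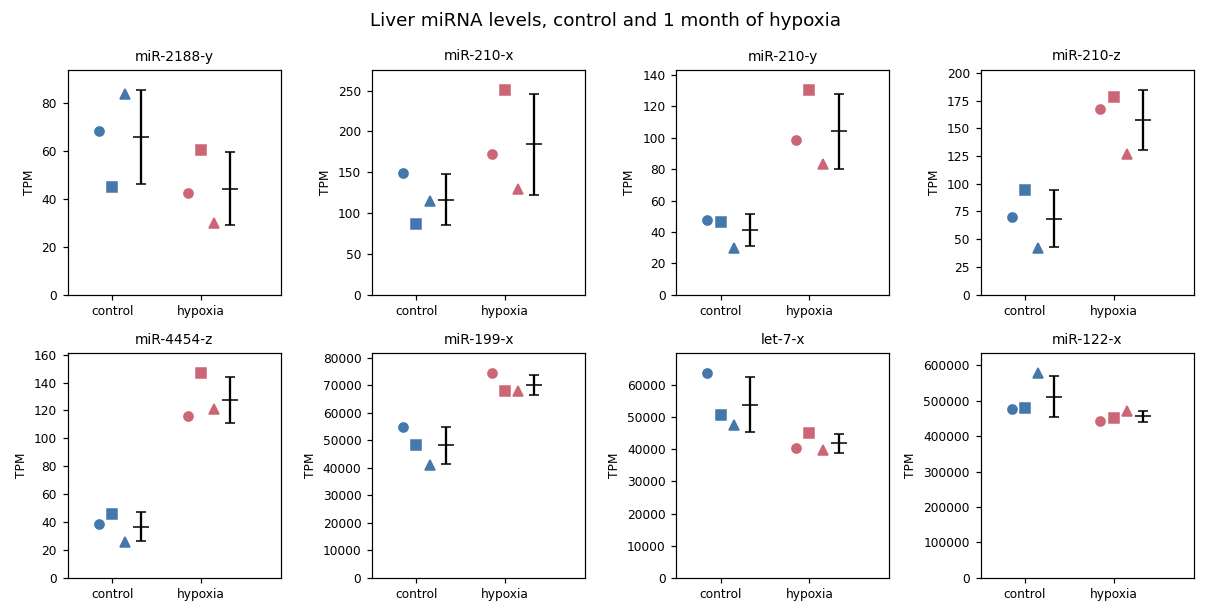
Levels of 8 miRNAs in TPM (vertical axes, linear and starting at 0) in each small RNA library of the control (blue) and hypoxia (red) groups. Circles, squares and triangles are replicates 1, 2 and 3, and the black bars give the mean and SD. The hypoxia libraries had a mean of 127.7 TPM for miR-4454-z against 36.7 TPM in control, the only row past the threshold in edgeR, while the groups of miR-2188-y overlapped.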

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

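The limma fits as first written, DESeq2, library totals, the distinct-sequence and known-miRNA fits and the fit without both small RNA libraries numbered 3 were chosen after seeing the data, and the other alternatives before. The count of 1398 genes was 826 with limma on log2(FPKM + 0.5), 771 and 846 with pseudocounts of 0.1 and 1, 734 without a trend and 476 with a 2-fold minimum (fewer genes by construction), and 361 to 2186 with 1 library left out. It was within 1.5 times with quantile normalization, array weights, no filter, a mean FPKM of at least 2, median-of-ratios scaling, library totals and DESeq2 (967 to 1849). The 1 miRNA row became 0 in limma as first written, with pseudocounts of 0.1 and 5, with quantile normalization and without a trend (40 to 52 rows at an unadjusted p under 0.05), 0 with library totals (42 rows), 3 with no filter, 6 with DESeq2 and 4 without the libraries numbered 3, and ranged from 0 to 0 with 1 library left out. Chosen after their values were seen, the 3 were miR-4454-z, miR-5108-z and miR-5119-z, and the 4 were miR-4454-z, miR-210-y and 2 predicted miRNAs. Over its 21 alternatives miR-4454-z had a log2 fold change of 1.49 to 1.83 and an adjusted p of 3.34e-10 to 0.236, past the threshold in 9. The median over tested miRNA rows was 0.13 in limma as first written and 0.03 in edgeR. The 13 list calls became 0 with estimated correlations and 4 with fry. The 2 camera runs used the same fit and differ only in the correlation setting. For bile acid and xenobiotic metabolism the estimated correlation was 7.92e-05, below the preset 0.01. Its unadjusted camera p still went from 0.00566 to 0.017, so a higher correlation cannot account for every lost call. The causes of the other shifts were not tested.

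Of the 98 named genes other than sod1, 72 kept direction and side of the threshold in all alternatives that keep every library. In all 6 fits that leave 1 library out, which have less power, 37 did. Without hypoxia replicate 1, 50 lost their side, and without control replicate 1, 2 did. With a library left out, sod1 ranged from -0.17 to 0.0016 (above 0 without control replicate 2) and miR-2188-y from -0.99 to -0.49. Without both libraries numbered 3 miR-2188-y was at -0.205 (adjusted p = 0.902; 0.322 to 0.902 over its alternatives). Values that turned sign were all uncalled, and the cause was not tested: myl1 (-1.38 to 0.0742 with a library left out); miR-30-x (-0.0699 at a mean TPM of at least 10, -0.0493 with distinct sequences, -0.136 with known miRNAs, -0.0536 without the libraries numbered 3, -0.131 to 0.172 with a library left out); miR-16-x (-0.00066 with known miRNAs). The value of miR-181-x was -0.065 with quantile normalization, -0.0287 at a mean TPM of at least 10, -0.00845 with distinct sequences, -0.0948 with known miRNAs and -0.0991 to 0.324 with a library left out. The value of miR-375-y was 0.0595 in limma as first written and without a trend, 0.06 and 0.0576 with pseudocounts of 0.1 and 5, 0.0624 with library totals, 0.016 with array weights, 0.0344 without the libraries numbered 3 and -0.151 to 0.1002 with a library left out. The list test turned for apoptosis with array weights (median 0.0207), glycolysis with no filter (0.055) and complement at a mean FPKM of at least 2 (-0.0322) and in fry (-0.0332). With a library left out it turned in some fits for the lists of fatty acid synthesis (median -0.099 to 0.0301), apoptosis (-0.0713 to 0.0677), skeletal muscle (-0.16 to 0.259), TCA cycle (-0.079 to 0.0141), leukocytes (0.00569 to 0.0719), complement (-0.0621 to 0.00684) and glycolysis (-0.0109 to 0.119).

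The labels do not state that the replicate numbers pair the samples. Deviations of same-numbered libraries correlated at -0.05, 0.04 and -0.04 in RNA-seq and 0.05, -0.0022 and 0.25 in small RNA. With 3 libraries per group these values cannot exclude pairing. A fit with the replicate block gave 1046 genes, 1 miRNA, 14 lists (the HIF list passed as well, adjusted p = 0.0487), -0.0962 for sod1 and -0.671 for miR-2188-y.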

Other observations

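The gene groups in this paragraph, the marker subsets and the tests below were chosen after the results were seen, and serine synthesis partly because its members were among the largest rises. Cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, rose in 14 of 26 cases and fell in 0 (edgeR, median 0.65), with aars1 higher by 2.02 on the log2 scale, sars1 by 1.52 and nars1 by 1.32. Of 9 genes of serine, asparagine and proline synthesis 6 rose and 1 fell (median 1.45). Among them psat1 rose by 1.78 and asns, which makes asparagine, by 1.52, while shmt2, which converts serine to glycine, fell by 0.51. Genes of ribosome assembly in the nucleolus had 10 higher and 1 lower of 52 (median 0.43), with nucleophosmin NPM1 higher by 1.60 and 1.68 at its 2 loci. Proteasome subunits had 9 higher and 0 lower of 80 in edgeR (median 0.20). With adjustment over these 6 groups the camera adjusted p was 4.16e-17 for the synthetases, 3.67e-12 for amino acid synthesis, 8.11e-09 for ribosome assembly and 5.25e-06 for the proteasome. With an estimated correlation the adjusted p was 0.0838, 0.0345, 0.165 and 0.0838 in the same order. Since the groups were chosen from the same data, no p-value in this paragraph counts as a test of them. Circadian clock genes (0 higher and 1 lower of 33 in edgeR) and the CCT chaperonin (0 of 15 in edgeR) both had a camera adjusted p of 0.135.

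Hemoglobin transcripts were lower in the hypoxia livers, by a mean of 1.05 (SE 0.244) on the log2 scale over 23 loci, 19 of them past the threshold. A loss of blood from the samples would lower other red cell transcripts by as much. The mean of 7 such transcripts (alas2, hemgn, rhag, slc4a1 and sptb loci) changed by -0.139 (SE 0.198), which lies 0.909 (SE 0.184) above the globins. They went both ways, with slc4a1 at -0.577 and -0.264 and rhag at -0.486 and 0.0151. The others were alas2 at -0.0266, hemgn at 0.178 and sptb at 0.351. All 20 other members of the red cell list changed by a mean of -0.0269 (SE 0.0989). Whether other liver cells express some of these 20 was not tested, so their mean is not used against a loss of blood. Reads moved between near-identical copies would leave the summed count level, and it changed by -0.95 (SE 0.204). The 7 transcripts are among the 20, so the same limit holds for them. Only if they come mainly from red cells do they argue against a loss of blood as the whole cause. The summed count argues against moved reads as the whole cause. A smaller loss of blood stays possible in any case. What lowered the globins stays open: fewer but younger red cells with more alas2 and hemgn, less globin RNA per red cell and an unrecorded difference between the groups were not tested, since these data hold no red cell counts or sorted red cells.

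Cell cycle genes were higher in the hypoxia livers, 24 of 56. More leukocytes, with these genes raised in proportion, would raise leukocyte markers by about the cell cycle median of 0.82. The median of 25 such markers was 0.152 (95% interval -0.089 to 0.259, from resampling the markers). That interval measures the spread between markers and not between libraries. Over all 55 leukocyte list members the mean change was 0.0557, with an SE between libraries of 0.077. Random lists of the same size matched on mean count held at most 9 higher genes in 10000 draws, which argues against scatter of single genes at low levels. The drawn genes were unrelated, so the draws cannot weigh a shift that cell cycle genes share in some libraries. With an estimated correlation (0.147 for this list) the camera adjusted p was 0.220. Without hypoxia replicate 3, 9 members were still called higher in edgeR. Which cells carry the rise was not tested, since whole liver does not separate dividing liver cells from a small fraction of other dividing cells, and both stay open.

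In the small RNA libraries, 14 tested miRNAs belong to families of a cluster known from placental mammals, and all 14 were highest in hypoxia replicate 3. Their median there was 5.32 times the mean of the other hypoxia libraries (2.45 to 6.79), against 1.01 for the other 496 rows. None (0) of the 14 was higher in all 3 hypoxia than in all 3 control libraries. The families were picked because some were seen to be high in this library, so neither count decides between mammalian small RNA mixed into it, related sequences of trout and a response to hypoxia, and all stay open. Summed over these rows the level was 58.55, 73.65 and 141.2 TPM in control replicates 1, 2 and 3 and 56.75, 65.84 and 383 TPM in hypoxia replicates 1, 2 and 3.

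The 6 libraries of each kind can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 1398 genes, 1 miRNA and 13 gene lists, and the highest of the other splits gave 0, 0 and 10 (1 split of the 10, the real one, reached each real count). Every split that mixed the groups gave 0 genes, but 5 to 10 lists by camera at its preset correlation. A camera call at that correlation is therefore weak evidence by itself. Mixed splits still hold part of any group difference, so these counts are not a rate of wrong calls.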
